A study of Mus musculus with 153 samples.

How the data were processed

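The series holds tail skin of 153 mice, snap frozen at 8 weeks of age with no treatment, 1 array per mouse. Per the series design, spretus males (Mus spretus) were crossed with FVB/N females lacking both copies of Hras, and the F1 daughters with FVB/N males that carried either no working copy or 1. In this series each mouse is labelled by Hras genotype (WT or HET), by sex and by the plate (1, 2 or 3) on which its array was processed. Groups were taken from the genotype label: 116 WT and 37 HET mice, of which 83 were males and 70 were females. The labels mark 2 arrays, both of WT males on plate 2, as outliers. These 2 were left out of the main comparisons, which rest on 151 mice (114 WT and 37 HET). Per the labels' protocols, RNA was extracted with Trizol and cleaned on a column, and biotin-labelled cRNA was hybridised to Affymetrix arrays.

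The deposited values are on the log2 scale, summarised per probe set by RMA, per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises the probes of a set. Its version, and any later adjustment, are not given in the sources used here. Of 35556 probe set rows, 171 were empty on every array and 35385 held values from 0.496 to 13.2. Array medians ran from 4.67 to 4.89, and the number of mice, not a read depth, limits the precision. The highest correlation of any 2 arrays over all probe sets was 0.986, and none was treated as a repeat of another.

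Gene names came from the annotation given for the probe sets, which held 1 gene symbol for 21201 probe sets, several for 1881 and none for 12303, which are unnamed here. Symbols were updated and chromosomes and gene order were read from a RefSeq gene table of assembly GRCm38.p6. The gene identifiers of 21168 probe sets matched that table and 33 did not. The array's own build is not given in the sources used here, so no coordinates are printed. Where a gene had several probe sets (1385 genes), the one with the highest mean was used. This gave 18810 genes. The Hras transcript is not reported here, so the genotype labels could not be checked against the targeted gene.

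Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend), with genotype, sex and plate in 1 model. A genotype by sex term was added in a second model. A gene was called when its Benjamini-Hochberg adjusted p over 18810 genes was under 0.05. Before the data were examined, 30 gene lists with 577 written members (500 of them measured) were fixed for cell types and pathways of skin. The neighbours of Hras, up to 100 measured genes on each side (185 in all), made a further list for the genotype comparison. Lists were tested with camera at a preset correlation between genes of 0.01, again with the correlation estimated from the data, and with fry. Files were read with the R package data.table (version 1.17.8).

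Co-expression was computed in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1; plots with matplotlib 3.10.9) on residuals after plate, sex and genotype. It used the 27 lists with at least 5 measured members, without the Y-linked and X-escape lists. The mean pairwise correlation of a list's members was placed among 10000 random lists matched on mean expression in 20 bins. A list score is the mean of its members' standardised residuals. Correlations of scores were tested by two-sided permutation tests with 100000 draws, with Benjamini-Hochberg adjustment over 351 pairs, or over 27 lists for the gene Lgr5. The smallest p these permutations can give is 1e-05. Each correlation was repeated within each plate, and without the 2 mice farthest from the median of a list score. That score was the one of the pair's first list, in the order the lists were fixed, or of the list set against Lgr5. The other variable was not used to choose the mice.

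The genes named were chosen by a rule fixed before the data were examined. It takes up to 8 called genes with the largest rise and up to 8 with the largest fall, with one sign on all 3 plates. It adds up to 3 called members of each list with the smallest p, the Ras genes in the genotype comparison, and the 5 smallest p-values where fewer than 5 genes passed. For correlations it takes the 6 most positive and 4 most negative pairs and the 3 lists most strongly correlated with Lgr5. Genes named outside the rule are said to be.

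The fits were tested on simulated arrays with the real gene means, spreads and design (18810 genes, 200 of them changed). For genotype, 81 of 100 genes changed by 0.2 (log2) and 99 of 100 changed by 0.4 were recovered. For sex the numbers were 80 and 100 of 100, and for the interaction 17 and 79 of 100. The largest number of unchanged genes called in one simulation was 10. A list shifted by 0.1 was called in both comparisons, with no other list called, but the simulated genes varied independently, unlike those of real lists. In the co-expression simulation both lists made to vary together passed and none of 25 others did.

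Alternatives covered the outlier arrays, the plate term, single plates, single sexes and genotypes, scaling between arrays, dim genes, the handling of probe sets, the variance model, array weights and covariates for tissue make-up. Some were chosen after seeing the data, as the closing section says. The covariates were list scores of the values as deposited. Scores of residuals, tried first, could not carry a group difference and were replaced after their counts had been seen. To count how often other splits give as large a result, genotype labels were shuffled within plate and sex, and sex labels within plate and genotype (within plate alone for the comparison of spread between the sexes), in 100 splits including the real one.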

Results

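Gene expression was measured in tail skin of 151 backcross mice with either both copies of Hras (WT, 114 mice) or 1 null copy (HET, 37 mice). Hras encodes a small GTPase of the growth factor signalling pathway. Of these mice, 81 were males and 70 were females. The arrays were processed on 3 plates with 49, 46 and 56 mice, of which 18.4%, 21.7% and 32.1% were HET and 61.2%, 54.3% and 46.4% were male. Every mouse carried the sex-linked transcripts of its labelled sex. Xist, the RNA that silences an X chromosome in females, lay between 9.32 and 10.9 in females and between 1.80 and 5.23 in males on the log2 scale. Eif2s3y, a Y-linked translation factor gene, lay between 2.17 and 3.67 in females and between 7.95 and 9.19 in males.

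The first comparison asked which transcripts differ between HET and WT skin. Most of the called genes, 19 of 21, lay on chromosome 7, the chromosome of Hras. Sirt3, a mitochondrial deacetylase 16 measured genes before Hras, fell from 5.92 ± 0.27 (SD, n = 114) in WT to 5.55 ± 0.40 (SD, n = 37) in HET mice, a difference of -0.36 ± 0.06 (SE, log2, limma adjusted p = 3.9e-05). Dhcr7, the last enzyme of cholesterol synthesis, differed by -0.32 ± 0.05 (SE), and its neighbour Nadsyn1, an enzyme of NAD synthesis, by -0.26 ± 0.05 (SE). Ano9, a membrane scramblase gene 3 measured genes before Hras, was higher in HET mice by 0.36 ± 0.07 (SE). Lrrc56, the next measured gene after Hras, was higher by 0.21 ± 0.04 (SE).

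In all, 21 of 18810 genes were called, 6 higher and 15 lower in HET skin, and 1235 had an unadjusted p under 0.05. Of the called genes, 19 lay on chromosome 7, none farther than 250 measured genes from Hras in the GRCm38.p6 gene order. The neighbours of Hras held 10 calls among 185 genes (5.41%), against 11 among 18625 other genes (0.059%). The odds ratio was 96.5 (Fisher's exact test, two-sided, p = 2.1e-15). The test counts genes as independent, but the called chromosome 7 genes varied together between mice, so its p overstates the evidence. By distance, 10 of the 185 genes within 100 places of Hras were called, 6 of the next 100 and 3 of the 100 after those, and none of the chromosome 7 genes beyond. All 21 differences had one sign on all 3 plates, but the genes were called on these same mice, which favours such agreement. For Sirt3 the differences were -0.11, -0.58 and -0.37 on plates 1, 2 and 3. Fitted alone with limma, plates 1 and 3 called 0 genes (887 and 1809 at an unadjusted p under 0.05) and plate 2 called 18, 11 of them among the 21. With each array centred on its median 20 genes were called, 8 higher and 12 lower. As a list the neighbours of Hras did not shift one way (camera adjusted p = 0.24), with 3 higher and 7 lower, or 17 and 15 adjusted over the list alone.

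**Figure D1:**
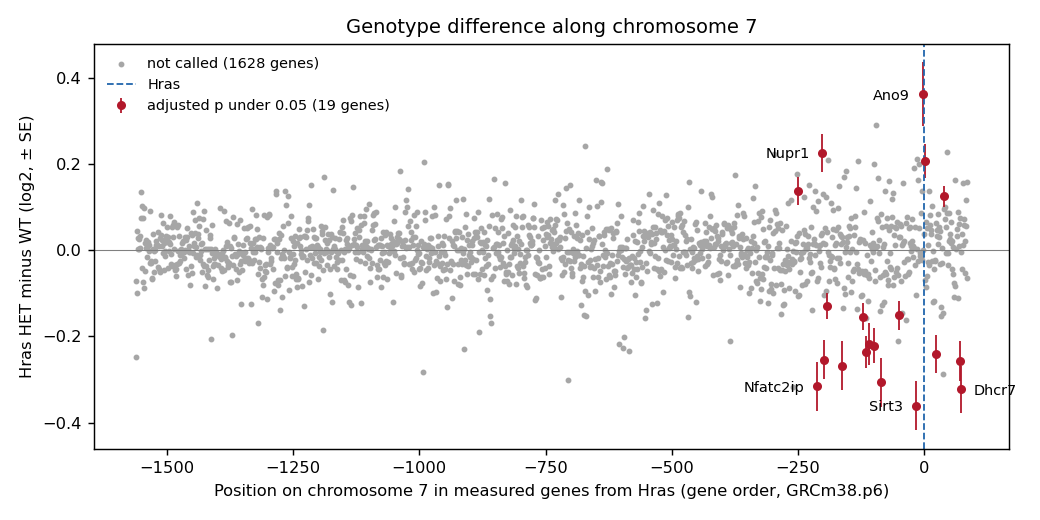
HET minus WT difference (log2, y axis) of each measured gene on chromosome 7 against its position in measured genes from Hras (x axis, gene order in GRCm38.p6). The 19 called genes (red, with SE) lie within 250 places of Hras and include Sirt3 at -0.36 and Ano9 at 0.36, and the other genes (grey) were not called.

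The other genes that fell most were Nfatc2ip (-0.32 ± 0.06, SE), Uros, the uroporphyrinogen synthase of haem synthesis (-0.31 ± 0.06, SE), Zfp764 (-0.27 ± 0.06, SE), Slx1b (-0.25 ± 0.05, SE) and Chid1 (-0.24 ± 0.04, SE). The other genes that rose were Nupr1, a stress-induced nuclear protein gene (0.23 ± 0.04, SE), Mettl9 (0.14 ± 0.03, SE) and Ctsd, the lysosomal protease cathepsin D (0.13 ± 0.03, SE). All have adjusted p-values under 0.05 by limma, and all lie on chromosome 7. The small nucleolar RNA Snord52 on chromosome 17 rose by 0.26 ± 0.06 (SE, adjusted p = 0.014). Its means of 3.27 in WT and 3.53 in HET mice lay near the lower quartile of the arrays, so the size of this difference is uncertain. Pdx1 on chromosome 5, named after its values were seen, differed by -0.20 ± 0.05 (SE, adjusted p = 0.046). Adjusted over the genes outside chromosome 7 alone, an alternative chosen after seeing the data, neither passed: 0 genes were called, with 1035 at an unadjusted p under 0.05. The Ras gene Nras differed by -0.03 ± 0.02 (SE, adjusted p = 0.84).

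Among the gene lists, camera at the preset correlation called 8 of 31 in HET skin and 0 with an estimated correlation. The hair shaft and inner root sheath list, keratins and keratin-associated proteins of the growing hair, had a median difference of -0.23 with 3 of 30 members above 0 (adjusted p = 5.7e-08, and adjusted p = 0.62 with an estimated correlation). Within plates 1, 2 and 3 the median was -0.19, -0.040 and -0.32, called on plate 3 alone (adjusted p = 0.12, 0.46 and 1.2e-10). No member was called alone, nor when adjusted over the list alone. The macrophage and dendritic cell list had a median of -0.14, with 1 of 19 members above 0 (adjusted p = 2.1e-06, and adjusted p = 0.62 with an estimated correlation). The MAPK feedback and target list, genes switched on by signalling downstream of Ras, had a median of -0.04 with 5 of 22 members above 0 (adjusted p = 8.4e-05, and adjusted p = 0.10 with an estimated correlation), and 2 members were lower when adjusted over the list alone. Mast cell genes (median -0.08) and dermal fibroblast and matrix genes (-0.03) were called lower. Sebaceous gland lipid synthesis (0.05), melanocyte (0.09) and skeletal muscle genes (0.11) were called higher. With an estimated correlation, adjusted p-values of these 5 lists were 0.68, 0.83, 0.62, 0.68 and 0.83 in that order. The dermal fibroblast list had the opposite sign on plate 1 (0.044), on plate 2 (0.19, adjusted p = 2.1e-08) and in males alone (0.053), and -0.22 on plate 3. On plate 2 the macrophage list also turned (0.093), as did the melanocyte list (-0.025). In females alone the direction of the skeletal muscle list test turned, while its median kept its sign. The cholesterol synthesis list was not called (median 0.03), although its member Dhcr7 fell. Fry called none of the lists in one direction, and its mixed test called the neighbours of Hras alone (adjusted p = 2.7e-27).

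The second comparison asked which transcripts differ between the sexes. Beyond the sex chromosomes, genes of several metabolic enzymes were among those with the largest differences. Cyp2g1, a cytochrome P450 on chromosome 7, was 11.2-fold lower in males, at 8.17 ± 1.20 (SD, n = 70) in females and 4.73 ± 1.12 (SD, n = 81) in males (limma difference -3.49 ± 0.19, SE, log2, adjusted p = 7.8e-38). Carns1, the carnosine synthase, was 2.20-fold lower (-1.14 ± 0.10, SE) and Akr1c18, which inactivates progesterone, 2.16-fold lower (-1.11 ± 0.09, SE). Hsd11b1, which regenerates active glucocorticoid, was 1.90-fold higher in males (0.92 ± 0.08, SE, adjusted p = 2.6e-20). Hsd17b7, an enzyme of steroid and cholesterol synthesis, was 1.37-fold higher (0.46 ± 0.05, SE, adjusted p = 3.9e-15).

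**Figure D2:**
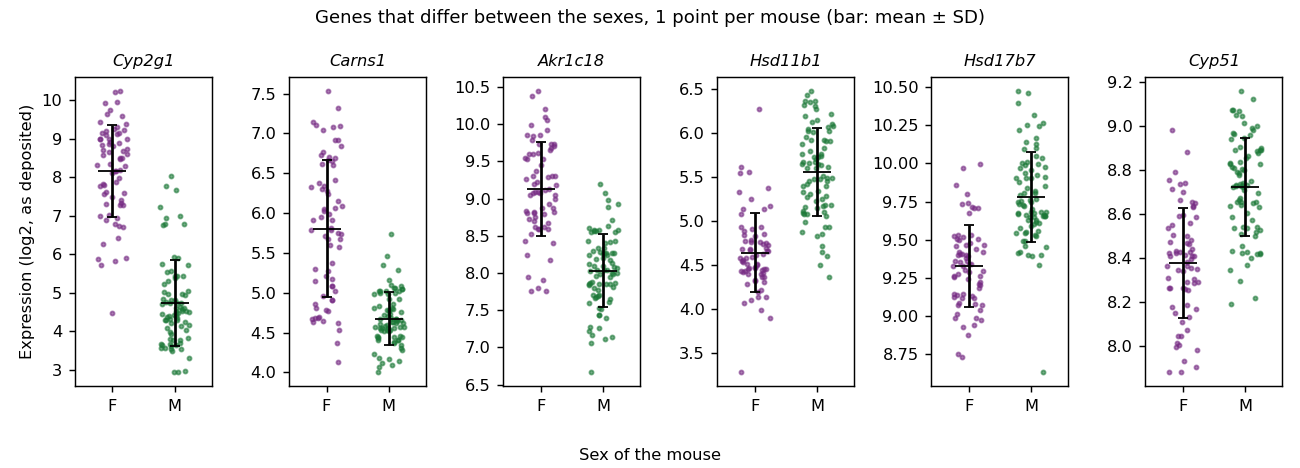
Expression (log2, y axis) of 6 genes in each mouse (points) by sex, with mean and SD (bars). Females (70 mice) had the higher mean for Cyp2g1, Carns1 and Akr1c18, and males (81 mice) for Hsd11b1, Hsd17b7 and Cyp51.

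In all, 680 genes were called, 207 higher and 473 lower in males, with 3077 at an unadjusted p under 0.05. Of the 680 called genes, 670 had one sign on all 3 plates, again in the mice they were called on. With each array centred on its median the split was 348 higher and 271 lower, and with quantile normalization 329 higher and 302 lower, so which direction had more calls depended on the scaling. On the autosomes 587 genes were called (182 higher, 405 lower), on the X chromosome 84 (16 higher, 68 lower) and on the Y chromosome 9, all higher. Single plates called 52, 73 and 115 genes. Only 8 called genes differed by at least 1 on the log2 scale, 4 of them autosomal. They were Xist (-7.15 ± 0.06, SE), the Y-linked Eif2s3y (5.87 ± 0.03, SE), Uty (4.64 ± 0.03, SE) and Kdm5d (3.66 ± 0.03, SE), together with Cyp2g1, Carns1, Akr1c18 and Scd3. In the other sex Xist (3.06), Eif2s3y (2.77), Uty (2.76) and Kdm5d (3.23) lay near or below the lower quartile of the arrays (3.02 to 3.20), where a level is not well measured, so the size of these differences is uncertain. The sebaceous desaturase Scd3 was higher in males by 1.26 ± 0.31 (SE, adjusted p = 0.0068), with 1.75, 0.11 and 1.80 on plates 1, 2 and 3.

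Of 11 measured genes that escape X inactivation, 8 were lower in males, among them the histone demethylase gene Kdm6a (-0.63 ± 0.02, SE) and Eif2s3x (-0.58 ± 0.02, SE). Of 7 measured Y-linked list members, 3 were higher in males. Both lists passed with the preset and the estimated correlation (estimated, adjusted p = 1.9e-42 and adjusted p = 3.7e-40). Adjusted over the list alone, 9 escape genes and 3 Y-linked genes passed. Other large differences were in Gm20815 (0.98 ± 0.10, SE) and Gm20809 (0.86 ± 0.11, SE) on the Y chromosome, in the alarm gene S100a8 (0.94 ± 0.29, SE), all higher in males, and in the wax synthase Awat2 (-0.77 ± 0.12, SE), Cyp2a5 (-0.71 ± 0.08, SE), the epidermal lipoxygenase Alox12e (-0.68 ± 0.11, SE) and the Hedgehog-binding Hhip (-0.65 ± 0.12, SE), all lower. Means of 3.08 and 2.63 in females for Gm20815 and Gm20809, and of 2.87 in males for Cyp2a5, also lay near or below that quartile, and the size of their differences is uncertain too.

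In the cholesterol synthesis list 4 of 15 members were higher in males and none lower (6 and 0 adjusted over the list alone), among them Cyp51 (0.35 ± 0.04, SE), Lss (0.30 ± 0.04, SE) and Msmo1 (0.13 ± 0.03, SE). The list was called higher at the preset correlation (median 0.07, adjusted p = 4.4e-08, and adjusted p = 0.063 with an estimated correlation). The sebaceous gland list was not called and went both ways, with 2 members higher, including Elovl3, an elongase (0.33 ± 0.06, SE), and 3 lower, including Awat2 and the desaturase Fads1 (-0.22 ± 0.05, SE). Of the 10 measured sex steroid genes, Hsd17b7 and 1 other were higher and Akr1c18 and the oestrogen-induced Greb1 (-0.44 ± 0.06, SE) were lower. Camera did not call the list (adjusted p = 0.082), but fry did (adjusted p = 0.0043). Adipocyte genes were called lower in males (median -0.08, 3 of 16 members called, adjusted p = 0.0092, and adjusted p = 0.36 with an estimated correlation). They included Adipoq, which encodes adiponectin (-0.30 ± 0.07, SE), Pnpla2 (-0.11 ± 0.03, SE) and Fabp4 (-0.26 ± 0.08, SE), which was 0.0042 on plate 1.

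All 30 hair shaft members had a negative difference (median -0.25, adjusted p = 8.7e-10, and adjusted p = 0.31 with an estimated correlation), 2 were called, and 14 when adjusted over the list alone. Within plates 1, 2 and 3 the median was -0.045, -0.45 and -0.24, not called on plate 1 (adjusted p = 0.43). The called members were Foxn1, a transcription factor of the hair shaft (-0.17 ± 0.05, SE), and Krt25 (-0.36 ± 0.10, SE). Of 18 hair follicle stem cell genes, 3 were called lower (6 adjusted over the list alone), namely Lgr5 (-0.29 ± 0.06, SE), Cd34 (-0.21 ± 0.06, SE) and Lhx2 (-0.17 ± 0.05, SE). That list had a median of -0.07 (adjusted p = 0.0075, and adjusted p = 0.30 with an estimated correlation). Of the epidermal genes, Tgm3 (0.22 ± 0.05, SE), Krt1 (0.11 ± 0.03, SE), Lamb3 (0.14 ± 0.03, SE) and Krt14 (0.07 ± 0.02, SE) were higher in males. The stress keratin and alarm list was called higher (median 0.21, adjusted p = 0.0012, and adjusted p = 0.36 with an estimated correlation), with Stfa3 (0.86 ± 0.16, SE) and Sprr2d (0.44 ± 0.09, SE) beside S100a8.

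Of 12 mast cell genes 4 were called lower and none higher (8 and 0 adjusted over the list alone), among them Kit, the stem cell factor receptor (-0.19 ± 0.04, SE), and the proteases Cpa3 (-0.33 ± 0.08, SE) and Mcpt4 (-0.30 ± 0.08, SE). The list had a median of -0.17 (adjusted p = 3.6e-06, and adjusted p = 0.20 with an estimated correlation). MHC class II genes, which present antigen, had a median of -0.16 (adjusted p = 0.014, and adjusted p = 0.31 with an estimated correlation), with Cd74 (-0.23 ± 0.06, SE) and H2-Ab1 (-0.20 ± 0.06, SE) called lower. In WT mice alone Cd74 was -0.28 and H2-Ab1 -0.25. In the fewer HET mice alone the values were -0.065 and -0.015, neither called. Among dermal matrix genes, 3 of 24 were higher, including the collagens Col3a1 (0.26 ± 0.05, SE) and Col1a1 (0.24 ± 0.06, SE), and 3 lower, including Postn, which encodes periostin (-0.18 ± 0.03, SE), and the list was not called. Mitochondrial respiration genes were called higher, with 3 of 18 members called and 6 adjusted over the list alone (median 0.03, adjusted p = 7.0e-05, and adjusted p = 0.063 with an estimated correlation). They were Ndufb8 (0.16 ± 0.04, SE), Cox4i1 (0.12 ± 0.03, SE) and Ndufa4 (0.16 ± 0.05, SE).

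At the preset correlation 16 of 30 lists were called between the sexes, 6 higher and 10 lower in males, 2 with an estimated correlation, and 12 by fry. The remaining calls were differentiated epidermis (median 0.02) and cell cycle (0.04), higher in males, and skeletal muscle (-0.17), cartilage, bone and tendon (-0.09), macrophage and dendritic cell (-0.09) and nerve and Schwann cell (-0.06), lower. With an estimated correlation their adjusted p-values were 0.62, 0.62, 0.74, 0.62, 0.62 and 0.36 in that order. Fry called the sex steroid list (adjusted p = 0.0043) and the Ras family and MAPK core (adjusted p = 0.013), which camera did not call. Its other calls were the Y-linked, X-escape, hair shaft, hair follicle stem cell, cholesterol, adipocyte, MHC class II, mast cell, nerve and mitochondrial lists. The cartilage list had the opposite sign on plate 1 (0.015), and the cartilage and skeletal muscle lists had it in HET mice alone. On plate 2 the direction of the macrophage list test turned, while its median stayed negative (-0.026). With skeletal muscle, adipocyte and fibroblast scores as covariates 7 lists were called, but the muscle and adipocyte lists were then adjusted for their own scores. Called members of other lists included Araf (-0.10 ± 0.03, SE) and Braf (-0.09 ± 0.02, SE) of the MAPK core, Il7r of T lymphocytes (-0.18 ± 0.05, SE), Drp2 of Schwann cells (-0.32 ± 0.07, SE), the clock-output factor Hlf (-0.26 ± 0.05, SE), Lcn2 (0.49 ± 0.13, SE), Ces1d (-0.50 ± 0.12, SE), Nqo1 (0.23 ± 0.06, SE) and Cbr2 (-0.26 ± 0.07, SE). Il7r was 0.0017 in HET mice alone.

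**Figure D3:**
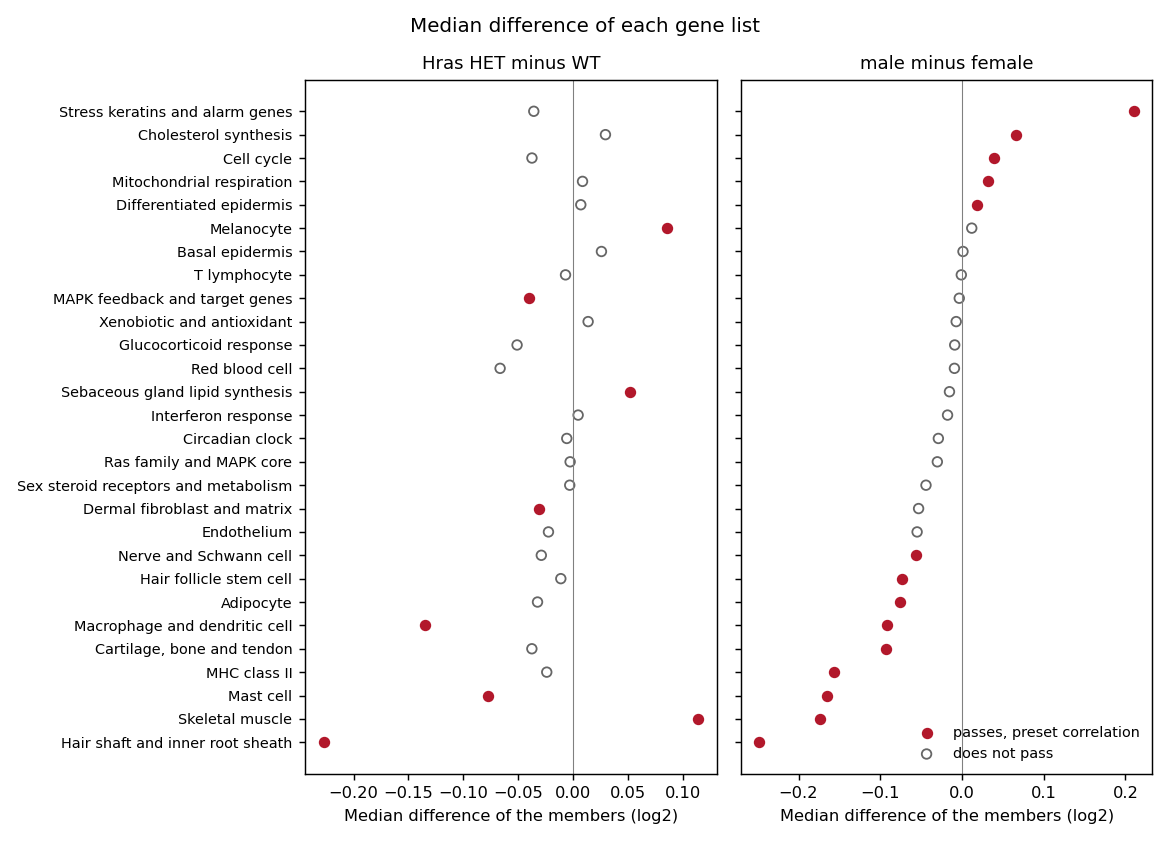
Median difference (log2, x axis) of the members of each gene list (y axis) for HET minus WT (left) and male minus female (right), leaving out the sex-chromosome lists and the neighbours of Hras. Filled points pass at the preset correlation, and hair shaft genes have the lowest median in both panels (-0.23 and -0.25).

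The third comparison asked whether the genotype difference depends on sex. No gene passed in limma (0 of 18810 called, 895 at an unadjusted p under 0.05). The 5 smallest p-values belonged to Gast, Ppp1r11, Cpq, Ncdn and Mlh3, none past the threshold. For Gast, which encodes gastrin, the HET minus WT difference was more positive in males than in females by 0.42 ± 0.10 (SE, log2, adjusted p = 0.58). For Ppp1r11, Cpq, Ncdn and Mlh3 the values were 0.45 ± 0.11, 0.76 ± 0.20, 0.19 ± 0.05 and 0.33 ± 0.09 (SE), each with an adjusted p of 0.62. Fitted alone with limma, females gave 10 genotype calls and males 0 (961 at an unadjusted p under 0.05), and no gene passed the test of that difference itself. Of 31 lists, camera called 5 on the interaction at the preset correlation and 0 with an estimated correlation (adjusted p = 0.95 for each), the dermal fibroblast and matrix list with the smallest p (median 0.18, adjusted p = 1.8e-06).

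The last comparison, after the network theme of the series title, asked which gene groups vary together between mice once plate, sex and genotype are removed. Skeletal muscle genes moved most closely together, with a mean pairwise r of 0.82 over 26 members, followed by dermal fibroblast and matrix genes (0.65), hair shaft and inner root sheath genes (0.61), cell cycle genes (0.52) and endothelial genes (0.52). Of 27 lists, 24 lay at or above the 99th percentile of 10000 random lists. The other 3 were the sex steroid list (mean r 0.057), the xenobiotic and antioxidant list (0.026) and the Ras family and MAPK core (0.014). Within plates the muscle value was 0.84, 0.79 and 0.82, whereas cartilage, bone and tendon genes went from 0.55 and 0.38 on plates 1 and 2 to 0.16 on plate 3.

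Between lists, 147 of 351 pairs of scores correlated past the threshold, 96 positively and 51 negatively, and 134 of them had one sign on all 3 plates. Without the 2 mice farthest from the median on the first list of each pair, 132 of the 147 passed and none changed sign. The strongest pair was dermal fibroblast with macrophage and dendritic cell genes (Pearson's r = 0.78, Spearman's rho = 0.75, both with a permutation p of 1e-05, the smallest possible, and 0.79, 0.76 and 0.78 within plates). Fibroblast scores also rose with endothelium (r = 0.73, rho = 0.71) and with cartilage, bone and tendon (r = 0.63, rho = 0.66). Mast cell scores rose with endothelium (r = 0.65, rho = 0.63) and with macrophages (r = 0.64, rho = 0.62), and macrophage scores with endothelium (r = 0.64, rho = 0.62). Differentiated epidermis ran opposite to endothelium (r = -0.54, rho = -0.58) and to nerve and Schwann cell genes (r = -0.48, rho = -0.47). The circadian clock list ran opposite to hair shaft genes (r = -0.51, rho = -0.52, with -0.72, -0.33 and -0.45 within plates) and to cell cycle genes (r = -0.47, rho = -0.45). Within plates 1, 2 and 3, r was 0.77, 0.80 and 0.66 for fibroblast with endothelium, 0.61, 0.74 and 0.70 for fibroblast with cartilage, 0.72, 0.69 and 0.58 for mast cell with endothelium, 0.69, 0.81 and 0.47 for mast cell with macrophage, and 0.69, 0.76 and 0.52 for macrophage with endothelium. For the negative pairs it was -0.35, -0.63 and -0.64 for differentiated epidermis with endothelium, -0.49, -0.57 and -0.34 with nerve, and -0.42, -0.62 and -0.39 for clock with cell cycle. Each of these 10 pairs had a permutation p of 1e-05 for r and for rho, with an adjusted p of 7.5e-05 for r and 7.6e-05 for rho. Without the 2 farthest mice r was 0.76 for the strongest pair, 0.71, 0.62, 0.65, 0.64 and 0.59 for the other positive pairs, and -0.50, -0.47, -0.51 and -0.40 for the negative pairs, in the order given.

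**Figure D4:**
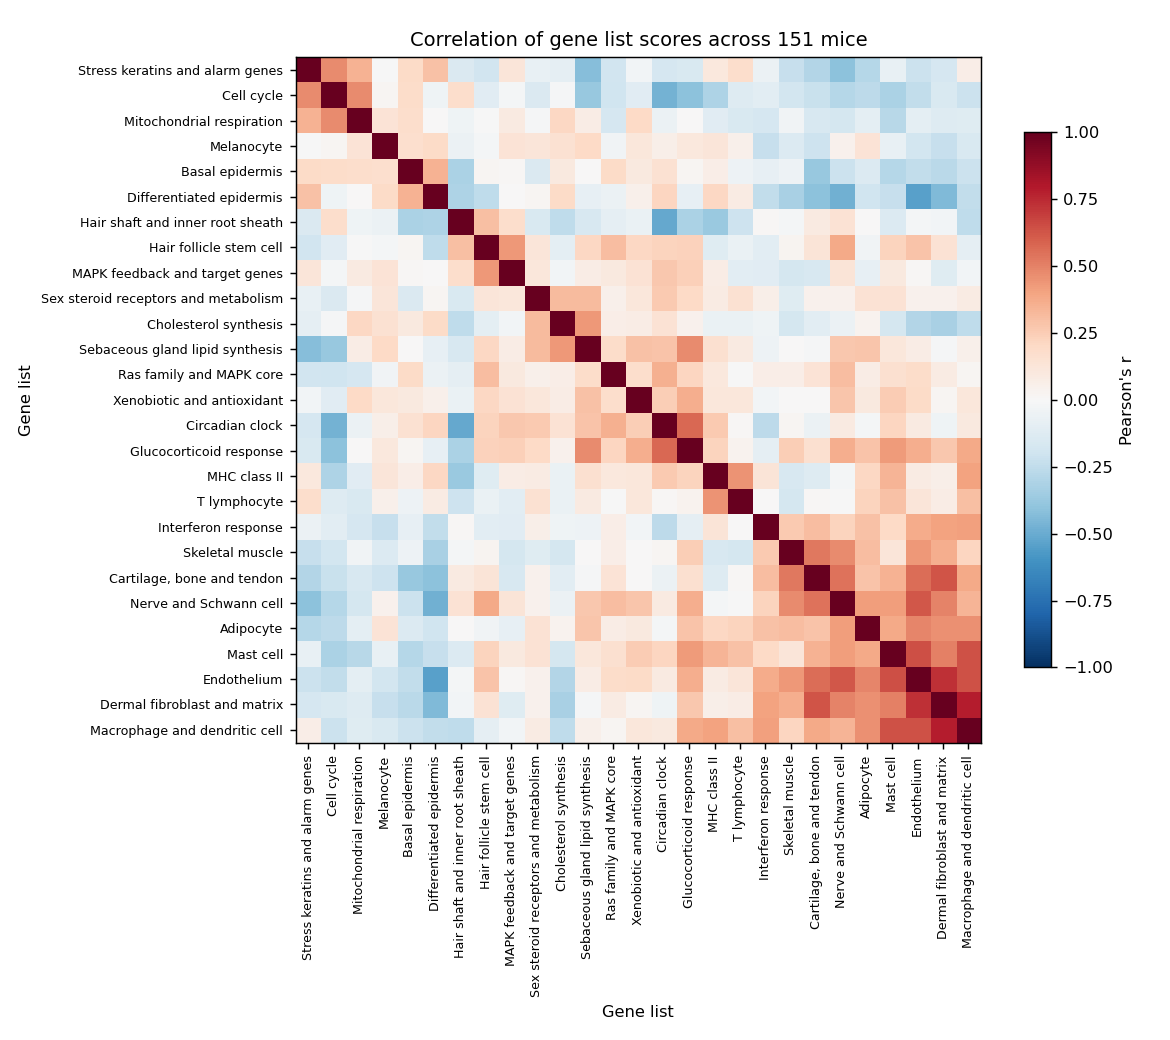
Pearson's r (colour) between the scores of 27 gene lists (both axes) across 151 mice after removal of plate, sex and genotype. Stromal and immune lists form a block of positive values, up to 0.78 for fibroblast with macrophage and dendritic cell genes, and differentiated epidermis is negative with endothelium (-0.54).

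Lgr5, which marks stem cells of the hair follicle, followed the hair shaft score most closely (r = 0.76, rho = 0.76, both with a permutation p of 1e-05, adjusted p = 9e-05). Within plates r was 0.79, 0.85 and 0.66, and without the 2 farthest mice 0.74. Next came the hair follicle stem cell list without Lgr5 itself (r = 0.46, rho = 0.46, same p, 0.40, 0.69 and 0.43 within plates, 0.43 without the 2 farthest mice). The circadian clock list ran the other way (r = -0.39, rho = -0.38, same p, -0.64, -0.40 and -0.15 within plates, -0.37 without the 2 farthest mice). In all 10 of 27 lists passed, 4 of them positively.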

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

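The tests of Hras dose, of probe brightness and of both plate explanations, the larger spread in HET mice, the use of the SD of list members as the spread for follicle tissue, and the alternative without chromosome 7 genes were chosen after the results were seen.

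Genotype calls gathered around Hras on chromosome 7. Chance can be excluded for their number, since 1 of 100 splits (the real one, 21 genes) gave as many and the highest other split gave 1. An effect of Hras dose on genes wherever they lie would not by itself give the excess among neighbours (Fisher's exact p = 2.1e-15). That test restates the gathering already seen and counts genes as independent, although the called genes varied together. Its p therefore overstates the evidence, and the test cannot exclude a further effect of Hras dose on genes elsewhere. By the parents that the series design names, a WT mouse would carry the spretus allele at Hras, while HET mice may carry either segment. Those parents would also give more HET than WT pups, yet the labels hold 116 WT and 37 HET mice, so this inference is uncertain. A segregating strain segment is a candidate explanation, as the 19 called genes varied together in the direction of their group difference. Among HET mice the mean oriented r was 0.39, above 100% of 10000 random sets of 19 genes. Among WT mice it was 0.21, also above 100%, and the difference was not tested. Of the 19 genes, 16 had a larger SD in HET mice. If WT mice carry the spretus allele, probes reading it dimmer would make most of the 19 genes brighter in HET mice. Only 5 of 19 were brighter, a lean the other way that did not pass (exact binomial test, two-sided, p = 0.064). The 19 genes varied together, so they are not independent draws for that test. Whether the difference lies in transcript level or in how probes bind the spretus allele cannot be told apart. A local effect of the null allele itself was not tested.

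The plates differed in almost nothing but sex-linked genes. Only 0.808% of genes had a plate p under 0.05, where 5% would be expected, and 4 passed adjustment: Eif2s3y (0.67 on plate 3 minus plate 1), Uty (0.51), Xist (-0.83) and Kdm5d (0.44). The plate 3 shifts had the sign that an adjustment for plate before deposit, taking no account of sex, would give. Over 93 called X and Y genes the shift followed the sex difference with a slope of 0.119 ± 0.0044 (SE across genes, which are not independent). The share of males was 0.148 higher on plate 1 than on plate 3. Over 587 called autosomal genes the slope was 0.210 ± 0.0078 (SE), so its size is not accounted for. The sign set for that test was corrected after the shifts, though not the slope, had been seen. Plate 2 also had a lower share of males than plate 1 (54.3% against 61.2%). Its shifts from plate 1 were small, at 0.044 for Eif2s3y, 0.021 for Uty, 0.035 for Kdm5d and 0.056 for Xist. They go against such an adjustment as the whole explanation. Wrong sex labels are argued against, since 0 mice had Xist or Eif2s3y in the range of the other sex, and no biological explanation was tested.

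Among the lists outside the sex chromosomes, hair shaft genes had the lowest median in both comparisons, but it was -0.040 and not called on plate 2 alone for genotype, and -0.045 and not called on plate 1 alone for sex. For genotype, the medians of hair follicle stem cell genes (-0.011, SD of members 0.058) and basal epidermis genes (0.026, SD 0.031) lay above the bound set before (-0.114) by more than that SD. The SD of members is not the error of a median. The stem cell genes also varied together only weakly between mice (mean pairwise r 0.13, against 0.61 for hair shaft genes), so they gauge follicle tissue poorly. Less follicle tissue as the whole cause therefore stays open for genotype. For sex it also stays open, since the stem cell median (-0.074, SD 0.094) lay within its spread of the bound (-0.124). Lgr5 was at -0.29, Cd34 at -0.21 and Lhx2 at -0.17, although basal epidermis genes were at 0.0013. Members that vary together between mice may account for the list p-values. By genotype, 9 of 100 splits gave as low a camera p (real 1.8e-09, lowest other 1.8e-33). By sex, 13 of 100 did (real 8.7e-11, lowest other 1.6e-19), so the splits do not exclude chance for either camera result. Fry, which allows for correlation between members, called the hair shaft list for sex (adjusted p = 0.015) and not for genotype (adjusted p = 0.52). For sex the tests therefore disagree. A difference in hair growth between the sexes was not tested.

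The number of sex calls is not explained by chance, with 1 of 100 splits (the real one, 680 genes) as large and 6 genes in the highest other. For sex lists 2 of 100 splits gave 16 lists or more, the highest other 17 and the median of the others 7. The real count includes the Y-linked and X-escape lists, which follow from the sex labels themselves. The splits therefore do not settle whether chance can give the calls of the other lists. For genotype lists 38 of 100 gave 8 or more, the highest other 15 and the median of the others 6, so chance cannot be excluded. For the interaction the real count was 0, so all 100 splits had to give as many and their number decides nothing (highest other 2).

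Genotype differences of 5 lists differed between the sexes by camera at the preset correlation on the interaction term. Dermal fibroblast and matrix genes (adjusted p = 1.8e-06, median 0.18, 24 of 24 members above 0), skeletal muscle genes (adjusted p = 0.0095, median 0.22, 26 of 26), MHC class II genes (adjusted p = 0.024, median 0.13, 7 of 7) and cartilage, bone and tendon genes (adjusted p = 0.039, median 0.06, 14 of 17) had a more positive difference in males, and mitochondrial respiration genes a more negative one (adjusted p = 0.033, median -0.04). With an estimated correlation none passed (adjusted p = 0.95 for each).

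Signal also appeared among the 14184 probe sets without 1 gene symbol, which no comparison used. The same model was fitted to them separately, with p-values adjusted over these probe sets alone. There 8 were called between genotypes (6 higher and 2 lower in HET mice). Between the sexes 171 were called (94 higher and 77 lower in males).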

How the results depend on the processing

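The alternatives without the unlabelled array least like the others, without chromosome 7 genes, with the hair shaft score as a covariate and without X and Y genes were chosen after seeing the data. Arrays carry no read depth, and dim genes were limited by background. Genotype calls (21) ran from 0 to 26 and kept within 1.5 times under 15 of 20 alternatives, sex calls (680) from 26 to 843 under 16 of 20, and within-list co-expression (24 lists) from 21 to 24 under 9 of 9. The alternatives for the Hras transcript and the seed correlations with Hras were not run. No other scaling reversed a named gene or list, but the split of sex calls moved from 207 higher and 473 lower to 348 and 271 (arrays centred) and 329 and 302 (quantile). WT-102, the least alike unlabelled array, left 23 genotype and 644 sex calls when removed. Without X and Y genes 565 sex calls passed.

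Plates alone hold fewer mice. Plate 1 called 0 genotype genes, 52 sex genes, 1 interaction gene, 3 genotype lists, 9 sex lists, 57 list pairs and 4 Lgr5 lists. Plate 2 called 73 sex genes, 4 genotype lists, 82 pairs and 6 Lgr5 lists. Plate 3 called 0 genotype genes, 115 sex genes, 70 pairs and 3 Lgr5 lists. Females alone called 10 genotype genes, males alone 0 with 3 genotype lists, and HET mice alone 26 sex genes and 7 sex lists, again with fewer mice. With an estimated correlation 0 genotype and 2 sex lists passed. With tissue scores as covariates 5 genotype and 7 sex lists passed; the muscle, adipocyte and fibroblast lists were there adjusted for their own scores, which by construction takes their medians towards 0. Without chromosome 7 genes 0 genotype genes passed, since removing the 19 calls there lowered the rank that the adjustment gave to the other 2 genes.

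Signs turned as follows; apart from those 3 lists with tissue scores, the cause was not tested. Among genes (log2), Fabp4 (sex, plate 1 alone) was 0.0042, Il7r (sex, HET alone) 0.0017 and Nras (genotype, plate 3 alone) 0.0030. Among genotype list medians, dermal fibroblast was 0.044 on plate 1, 0.193 on plate 2, 0.053 in males and 0.011 with tissue scores, macrophage 0.093 and melanocyte -0.025 on plate 2, and skeletal muscle 0.0054 in females. Among sex list medians, cartilage was 0.015 on plate 1 and 0.016 in HET mice, skeletal muscle 0.040 in HET mice and -0.0011 with tissue scores, MHC class II -0.015 in HET mice, macrophage -0.026 on plate 2 and adipocyte -0.0097 with tissue scores. For muscle in females and for every negative sex list value given here, the direction of the test turned while the median kept its sign.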

Other observations

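Among the 100 genes that varied most between mice, by residual SD after plate, sex and genotype were removed, 14 were of the skeletal muscle list, 6 of the stress keratin and alarm list, 3 of cartilage, bone and tendon, 2 of the hair shaft, 1 of the sebaceous gland and 1 of adipocytes, and 73 were in no list. The largest SDs on the log2 scale were those of Krt6b, a keratin of stressed epidermis (2.06), the carboxylesterase Ces1f (2.00), Scd3 (1.93), the complement receptor Cr2 (1.77) and S100a8 (1.77), against a median of 0.223 over all genes. These genes were chosen after their values were seen.

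Both tests of a difference in spread between the sexes were written before the result was seen. X-linked genes varied more between males than between females. The median log2 ratio of male to female variance was 0.14 over 719 X-linked genes and 0.058 over autosomal genes, and 63.8% against 56.5% of genes had the larger variance in males. The difference was 0.086, and 1 of 100 splits of the mice by sex within plate, the real one, gave as large a value, with 0.071 in the highest other. Expression level is argued against as the reason, since the X-linked median lay above 100% of autosomal lists matched on mean expression. The result is consistent with the hypothesis that a single segregating X in males, against a pair of X chromosomes in females, adds to the spread, but the backcross origin of each mouse's X was not analysed here.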
